A study of Arabidopsis thaliana with 18 samples.

How the data were processed

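Leaf RNA of Arabidopsis thaliana was hybridised by the submitters to 18 Affymetrix ATH1 arrays with 1 colour, 3 in each of 6 groups given by the labels: Col-0 or OE (lines OEEV47-1 and OEEV47-2 that over-express StZFP2, pooled per the sample labels), each unwounded, 1 h after wounding and 6 h after wounding. Per the submitters' processing notes the values were made with MAS5, whose version is not stated, and the deposited values are signal intensity on a linear scale, scaled by the authors so that the mean of each array without the extreme 2% at either end is 500. The table held 22810 probe sets, of which 64 were controls and 22591 carried a locus. By identifier, 22091 probe sets had a locus found in the reference table of gene symbols. Of the probe sets, 21557 mapped to 1 gene and 1034 had a name that marks probes shared between genes. A further 90 columns of values per array, 18 in each set, were not used here, because their names do not state which sample each belongs to. Presence calls were not used here, so dim signals were judged by the percentile of their array.

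Groups, comparisons, gene lists, the rule for naming genes and most of the other settings tried were fixed before the data were examined. Signals were taken to log2 as deposited, and a probe set was kept when its signal reached the 40th percentile of its array on at least 3 of the 18 arrays, which left 14823. A limma model (version 3.58.1 in R 4.3.3) with 1 mean per group was fitted to all 18 arrays, with 12 residual degrees of freedom, variance moderation with a trend on mean signal, and Benjamini-Hochberg adjustment over the 14823 probe sets in each of 11 contrasts; calls were made at an adjusted p below 0.05. Replicate letters were not used as a block in the reported values. The number of arrays limits the precision, and all limma, camera and fry tests were two-sided. Each fold is between means of log2 signal, with its standard error; a fold against a group whose arrays all lay below the 40th percentile is given as a lower bound, computed from that percentile, without a size, or as a value whose size is said to be unresolved. Contrasts that share arrays were not correlated with each other.

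For each contrast, genes were named from probe sets with an adjusted p below 0.05, a log2 change of at least 1 in size, a match to 1 gene and no overlap between the arrays of the groups, as the 10 highest and the 10 lowest; for the contrast over all conditions the lack of overlap had to hold within each of the 3 treatment labels, and the interactions had no such condition. Members of the fixed lists were also named. A gene with several probe sets was given by the one with the highest mean. Lists were fixed for jasmonate synthesis, JAZ repressors, jasmonate breakdown and conjugation, jasmonate-responsive defence, jasmonate-ethylene defence, C1-2i zinc finger genes, WRKY factors, ERF and CBF factors, touch and calcium, indolic glucosinolates, aliphatic glucosinolates, salicylic acid, ethylene, abscisic acid and cold, photosynthesis, the clock, sugar starvation, auxin, heat shock, phenylpropanoids and anthocyanins, senescence, floral organs, guard cells and phloem, and roots. Of 348 members of the 24 lists 323 were matched by locus and symbol, and 23 lists had at least 3 measured members. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry in its directional form, over 1 probe set for each of 14197 genes, with Benjamini-Hochberg adjustment over lists within a contrast.

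The other settings fixed beforehand were the replicate letter as a block, quantile normalization, subtraction of array medians, log2 after addition of 16, no filter, a filter at the 60th percentile, no variance trend, array weights, a model of only the arrays compared, and each array left out in turn. Chosen after seeing the data were a model of the 9 Col-0 arrays alone, a model of 15 arrays without the OE arrays lettered C, and a comparison of the 9 OE with the 9 Col-0 arrays with no term for treatment. The models were tested on simulated data with 200 of 14823 probe sets changed. In the contrast at 1 h in Col-0 they recovered 52% of changes of log2 1 and 85% of log2 2 with 18 arrays, and 68% and 85% with the 9 Col-0 arrays. The simulated noise was independent and of equal size on all arrays, unlike the scatter of the arrays labelled OE. These shares therefore do not give the recovery in the real data. Gene ontology terms of 5 to 500 genes in the platform annotation, 712 in all, were tested with a one-sided Fisher's exact test over 9028 genes with a term. Figures were drawn with matplotlib 3.10.9 in Python.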

Results

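Leaf RNA of Arabidopsis thaliana was measured on 18 Affymetrix ATH1 arrays, 1 sample per array. The plants were the wild type Col-0, or lines that over-express StZFP2, a potato gene for a C2H2 zinc finger protein. The sample labels give a pool of the lines OEEV47-1 and OEEV47-2, while the series design names the lines separately. For each genotype, 3 arrays lettered A, B and C came from unwounded leaves, 3 from leaves 1 h after wounding and 3 from leaves 6 h after wounding. The question of the series is how over-expression of StZFP2 alters the response to a wound. The median signal of an array lay between 127.5 and 161.1, and the number of arrays limits the precision of every comparison. The labels do not say whether the replicates of a group came from separate plants, so the p-values measure only the spread between these samples, which may be technical. No probe set for the potato transgene was measured, so its level was not checked in any sample. The labels name no unwounded group at 6 h and do not give the hour at which any leaves were taken. The Col-0 contrasts at 6 h therefore do not separate wounding from time of day.

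The Col-0 arrays at 1 h and at 6 h were closest to the other arrays of their labelled group, while several arrays labelled OE were closest to an array of another treatment label. Across the 14823 probe sets, the correlation of log2 signals between arrays of a group was 0.946 to 0.968 in unwounded Col-0 leaves, 0.972 to 0.977 at 1 h and 0.973 to 0.977 at 6 h. Genes are not independent replicates, so these values only describe the arrays. In the arrays labelled OE it was 0.922 to 0.983 in the controls, 0.934 to 0.970 at 1 h and 0.89 to 0.975 at 6 h. The arrays labelled OE control A and B matched the array labelled OE 6h wound C (0.975 and 0.980), and these 3 correlated with the Col-0 6 h arrays at 0.961 to 0.971, against 0.876 to 0.892 with the unwounded Col-0 arrays. The array labelled OE control C was closest to the arrays labelled OE 1h wound A and B (0.974 and 0.973). The array labelled OE 1h wound C was closest to the arrays labelled OE 6h wound B and A (0.978 and 0.973). Groups were kept as labelled, so the words "arrays labelled OE" stand for the labels alone in each comparison with a treatment term.

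**Figure D1:**
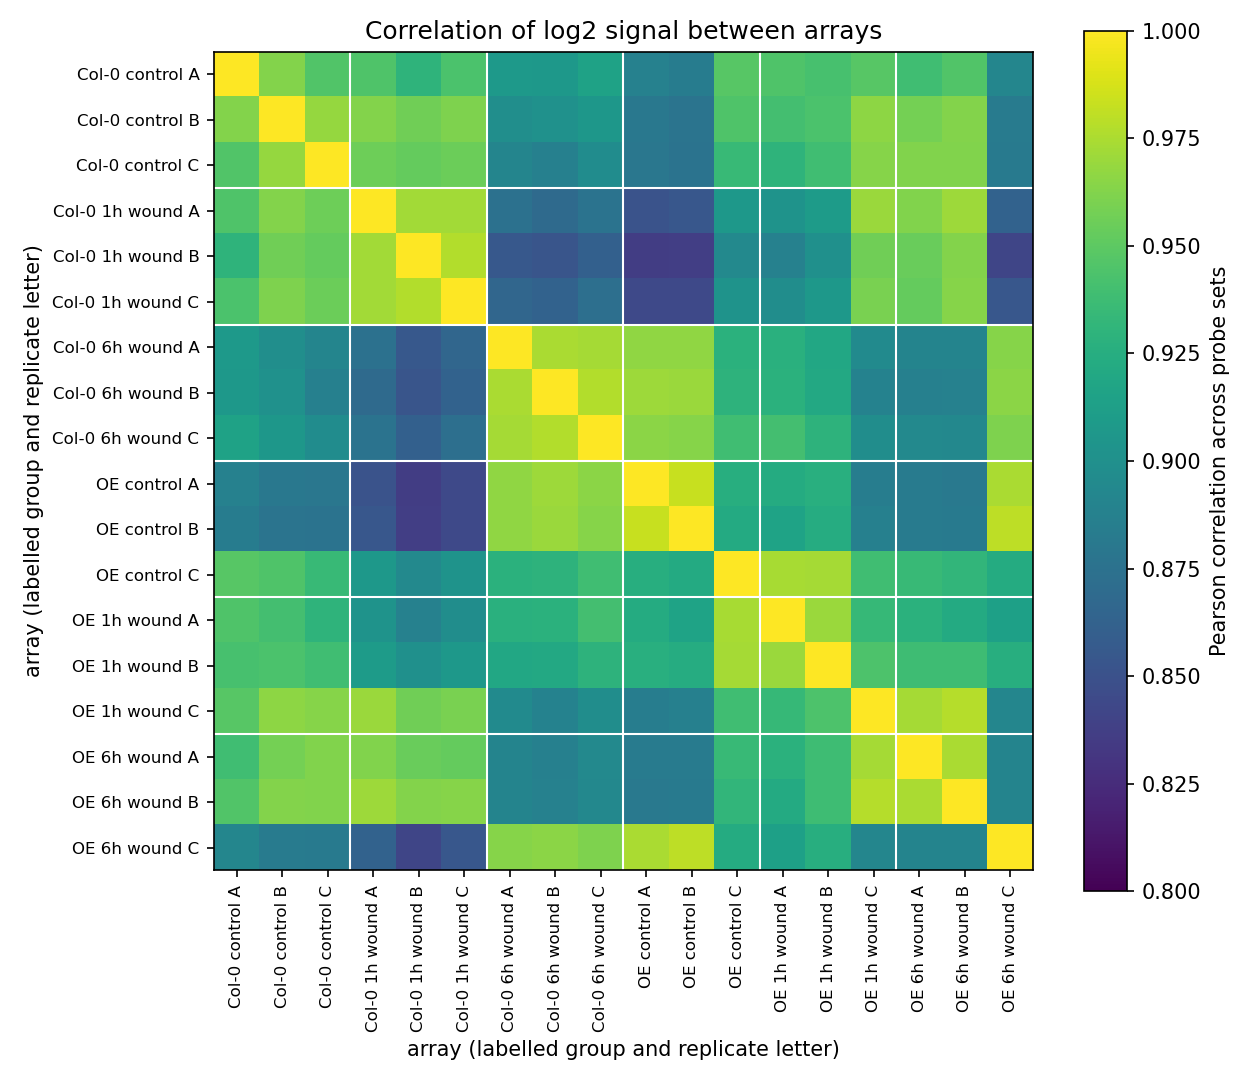
Correlation of log2 signal between each pair of the 18 arrays, over 14823 probe sets, with arrays in the order of their labels on both axes and the coefficient as colour. The Col-0 6 h arrays form a block on the diagonal (0.973 to 0.977), the unwounded and 1 h Col-0 arrays overlap in their correlations, and the arrays labelled OE control A and B and OE 6h wound C correlate with the Col-0 6 h arrays at 0.961 to 0.971.

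The early wound response of the wild type was read from Col-0 leaves 1 h after wounding against unwounded Col-0 leaves. In the model of all 18 arrays 4 probe sets rose and 0 fell (limma with Benjamini-Hochberg adjustment; 2103 had an unadjusted p below 0.05). The mean signal of B120 (AT4G21390), a receptor-like kinase, was 122 ± 29.8 in unwounded and 683 ± 82.5 in wounded leaves (SD, n = 3 each), a log2 change of 2.50 ± 0.40 (SE; limma adjusted p = 0.0452). AT1G59910 rose by 1.25 ± 0.19 and AT1G21010 by 1.10 ± 0.16 on the log2 scale (limma adjusted p = 0.0375 and 0.035). LSH1 (AT5G28490) rose (limma adjusted p = 0.035), but its unwounded signals, 11.8 ± 4.06, all lay below the 40th percentile of their arrays, so the size of its fold is not resolved. The count fell to 0 without any one of the arrays Col-0 control A, B or C or Col-0 1h wound C.

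The scatter of the arrays labelled OE enters the error of that model, so the 9 Col-0 arrays were also fitted alone, an alternative chosen after seeing the data. In that fit 866 probe sets passed at 1 h, 540 higher and 326 lower, among them the 4 above. Of 16 WRKY factors, transcription factors of defence and stress, 11 rose and 1 fell. WRKY18 rose by 2.07 ± 0.17, WRKY48 by 1.92 ± 0.20 and WRKY40 by 1.75 ± 0.18, while WRKY70, which is tied to salicylic acid, fell by 1.36 on the log2 scale. The camera test over the WRKY list gave an adjusted p = 4.72e-11 in the Col-0 fit, and adjusted p = 0.0391 with an estimated correlation. In the model of 18 arrays 0 of the 16 passed over all genes, 9 rose and 1 fell adjusted over the list alone, and camera gave an adjusted p = 1.35e-08, and adjusted p = 0.284 with an estimated correlation.

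Jasmonate genes also moved early in the Col-0 fit. Of 15 measured genes of jasmonate synthesis 5 rose (10 rose and 1 fell adjusted over the list alone), among them the allene oxide cyclase AOC3 (1.50 ± 0.24) and the lipoxygenases LOX4 (1.36 ± 0.22) and LOX3 (0.99 ± 0.21). Of 10 JAZ repressors of jasmonate signalling 3 rose (8 adjusted over the list alone), namely JAZ8 (1.69 ± 0.21), JAZ7 and JAZ1 (0.93 ± 0.22). Of 9 genes of jasmonate breakdown and conjugation 5 rose (6 adjusted over the list alone), with the jasmonoyl-isoleucine oxidases CYP94C1 at 1.46 ± 0.19, CYP94B1 at 1.37 ± 0.25 and CYP94B3 at 1.21 ± 0.31. The camera adjusted p of the 3 lists was 2.03e-05, 2.1e-08 and 3.21e-06, and adjusted p = 0.248, 0.199 and 0.239 with an estimated correlation. In the model of 18 arrays 0 members of these lists passed, with camera adjusted p = 0.00335, 6.01e-05 and 0.00543, and adjusted p = 0.347, 0.42 and 0.432 with an estimated correlation. None of the 12 genes of later jasmonate-responsive defence passed at 1 h in either fit, and 0 of 4 passed in the jasmonate-ethylene defence list.

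Other fast stress genes followed in the Col-0 fit. Of 16 touch and calcium genes 7 rose (10 adjusted over the list alone), among them the calmodulin-like genes CML37 (1.89 ± 0.29) and CML38 (1.68 ± 0.18) and the zinc finger gene SZF1 (1.34 ± 0.19). Of 10 C1-2i zinc finger genes, the family of plant C2H2 repressors that StZFP2 is set beside here, 4 rose (6 rose and 1 fell adjusted over the list alone). They were ZAT11, at least 3.05-fold over a group below the 40th percentile, ZAT18 (2.13 ± 0.35), ZAT10 (1.04 ± 0.20) and ZAT12 (0.90 ± 0.23). Of 17 ERF and CBF factors 4 rose (6 rose and 1 fell adjusted over the list alone), with ERF109 at 2.15 ± 0.27. Of 12 ethylene genes the synthases ACS8 (1.52 ± 0.22), ACS2 and ACS6 rose (3 adjusted over the list alone). The camera adjusted p of these 4 lists was 4.59e-08, 5.28e-05, 0.00028 and 0.0247, and adjusted p = 0.199, 0.182, 0.199 and 0.265 with an estimated correlation. NCED3, the key enzyme of abscisic acid synthesis, rose by 1.89 ± 0.29, as 1 of 16 genes of its list. Against these, 3 of 14 salicylic acid genes fell (PR1 by 1.70, PR5 by 0.91 and ICS1 by 0.91 on the log2 scale) and GRXC9 rose by 1.19 ± 0.18.

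At 6 h after wounding the wild type had moved much farther from the unwounded leaves. In the model of 18 arrays 2351 probe sets passed, 1329 higher and 1022 lower, and 1258 of them changed at least 2-fold. The highest included AT2G39920, at least 19.3-fold, the clock gene PRR5, at least 8.72-fold, AT1G56300, at least 29.7-fold, the lipid transfer protein LTP4 (6.26 ± 1.86, limma adjusted p = 0.0346) and the chlorophyll synthesis enzyme PORB (4.88 ± 1.00, limma adjusted p = 0.0123). PORB signal was 408 ± 128 in unwounded and 11550 ± 489 in wounded leaves (SD, n = 3 each). The unwounded LTP4 signal was 53.8 ± 55.4 (SD, n = 3), a mean below the 40th percentile of those arrays. The size of the LTP4 fold is therefore uncertain. The lowest included MYB47, at least 16.9-fold lower, MAPKKK19, at least 5.08-fold lower, the flavonoid enzymes F3H (−4.03 ± 0.46, limma adjusted p = 0.00147) and CHIL (−3.96 ± 0.58, limma adjusted p = 0.0046) and the clock gene LHY (−3.77 ± 0.78, limma adjusted p = 0.0123).

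Jasmonate genes moved in both directions at 6 h. Of 12 jasmonate-responsive defence genes 4 rose and 1 fell (5 and 5 adjusted over the list alone). The ribonuclease RNS1 (3.17 ± 0.59), the ornithine acetyltransferase NATA1 (2.72 ± 0.45), JAL35 (1.33 ± 0.30) and CORI3 (1.14 ± 0.25) rose, and the terpene synthase TPS04 fell by 3.08 on the log2 scale. Of the breakdown and conjugation genes 3 of 9 rose (3 rose and 2 fell adjusted over the list alone), with the sulfotransferase ST2A at 3.73 ± 0.77, JOX4 at 1.79 ± 0.57 and JOX3 at 1.58 ± 0.31. Of 15 synthesis genes 5 rose, among them LOX2 (0.74 ± 0.17) and AOC4 (1.02 ± 0.29), and 2 fell, LOX4 by 3.38 and OPR3 by 1.19 on the log2 scale (6 rose and 5 fell adjusted over the list alone). Of 10 JAZ repressors 4 fell below the unwounded level (6 adjusted over the list alone), namely JAZ7 (−3.02 ± 0.73), JAZ5 (−2.28 ± 0.59), JAZ6 (−1.83 ± 0.42) and JAZ2 (−1.44 ± 0.42). The list had a camera adjusted p = 7.02e-05, and adjusted p = 0.558 with an estimated correlation. Camera gave an adjusted p = 0.41 for the defence list, 0.892 for breakdown and 0.892 for synthesis, and 0 of 4 jasmonate-ethylene defence genes passed.

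Part of the regulators that respond fast to wounding fell below the unwounded level at 6 h. In the touch and calcium list 6 of 16 fell (7 adjusted over the list alone), with the calmodulin-like genes CML12 at −2.22 ± 0.45 and CML24 at −1.42 ± 0.44. In the WRKY list 4 of 16 fell (1 rose and 5 fell adjusted over the list alone), among them WRKY40 (−2.47 ± 0.64) and WRKY53 (−1.35 ± 0.34). In the ERF and CBF list 7 of 17 fell, with ERF2 at −2.43 ± 0.39, while CBF3 (3.51 ± 0.91) and RAP2.6L (0.74 ± 0.19) rose (2 rose and 7 fell adjusted over the list alone). In the C1-2i list ZAT6, AZF2 and ZAT5 fell (3 of 10; 4 adjusted over the list alone). The camera adjusted p was 3.17e-05, 0.0224, 0.0127 and 0.0127 for these 4 lists, and adjusted p = 0.558 for each with an estimated correlation. Of 14 salicylic acid genes PAD3 and CBP60G fell (5 adjusted over the list alone), and of 12 ethylene genes ACO4 fell (0 adjusted over the list alone).

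Metabolic groups and clock genes changed as well at 6 h. Of 18 phenylpropanoid and anthocyanin genes 7 fell and 0 rose (10 adjusted over the list alone), with F3H, FLS1 (−2.57 ± 0.37), CHS (−2.27 ± 0.38) and PAL2 (−1.33 ± 0.37). This list had a camera adjusted p = 2.05e-05, adjusted p = 0.189 with an estimated correlation and a fry adjusted p = 0.000401. Of 11 sugar starvation genes 4 rose (6 adjusted over the list alone), among them DIN10 (2.38 ± 0.72) and TPS10 (AT1G60140, 1.81 ± 0.43; camera adjusted p = 0.0083, and adjusted p = 0.558 with an estimated correlation). Aliphatic glucosinolate genes had 3 of 13 higher, with MAM1 at 1.23 ± 0.27 (4 adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.612 with an estimated correlation). In the indolic list CYP83B1, SOT16, CYP79B3 and MYB34 fell and CYP81F4 rose, 5 of 15. Photosynthesis genes moved little, with PETE1 and PSAD2 up, 2 of 24 (camera adjusted p = 0.0127, 0.0639 after subtraction of array medians, and adjusted p = 0.633 with an estimated correlation). Of 11 heat shock genes BAG6 and HSP17.4 rose while the heat shock factor HSFA2, HSP70, HSP90.1 and HSP101 fell. Of 16 abscisic acid and cold genes 3 rose and 4 fell, with COR15B at 2.63 ± 0.86 and RD26 at −2.53 ± 0.52. Of 17 auxin genes IAA2, IAA3, IAA6 and IAA7 fell. Among markers of other leaf states and cell types, SGR1 fell as 1 of 6 senescence genes, the guard cell channel KAT1 rose as 1 of 4 guard cell and phloem genes. Of the rest, 0 of 3 root genes passed, and 0 of 2 measured floral genes passed.

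Clock genes moved in opposite directions by phase. Of 11 measured, 4 rose and 4 fell (6 and 4 adjusted over the list alone). PRR5, PRR7 (1.93 ± 0.34), GI (1.90 ± 0.61) and the clock output gene GRP7 (3.78 ± 1.18) rose. The morning genes LHY, CCA1 (−1.84 ± 0.51), RVE8 (−2.02 ± 0.56) and RVE1 (−1.45 ± 0.42) fell. In the fit of the 9 Col-0 arrays 7 rose and 4 fell at 6 h, and 0 of the 11 passed at 1 h. In that fit the count at 6 h was 4294 probe sets, 2276 higher and 2018 lower, of which 2331 had also passed in the model of 18 arrays. The count at 6 h in the model of 18 arrays was 664 without Col-0 control B, 678 without Col-0 control C, 439, 473 and 869 without Col-0 6h wound A, B and C, and 3839 with the 6 compared arrays alone.

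**Figure D2:**
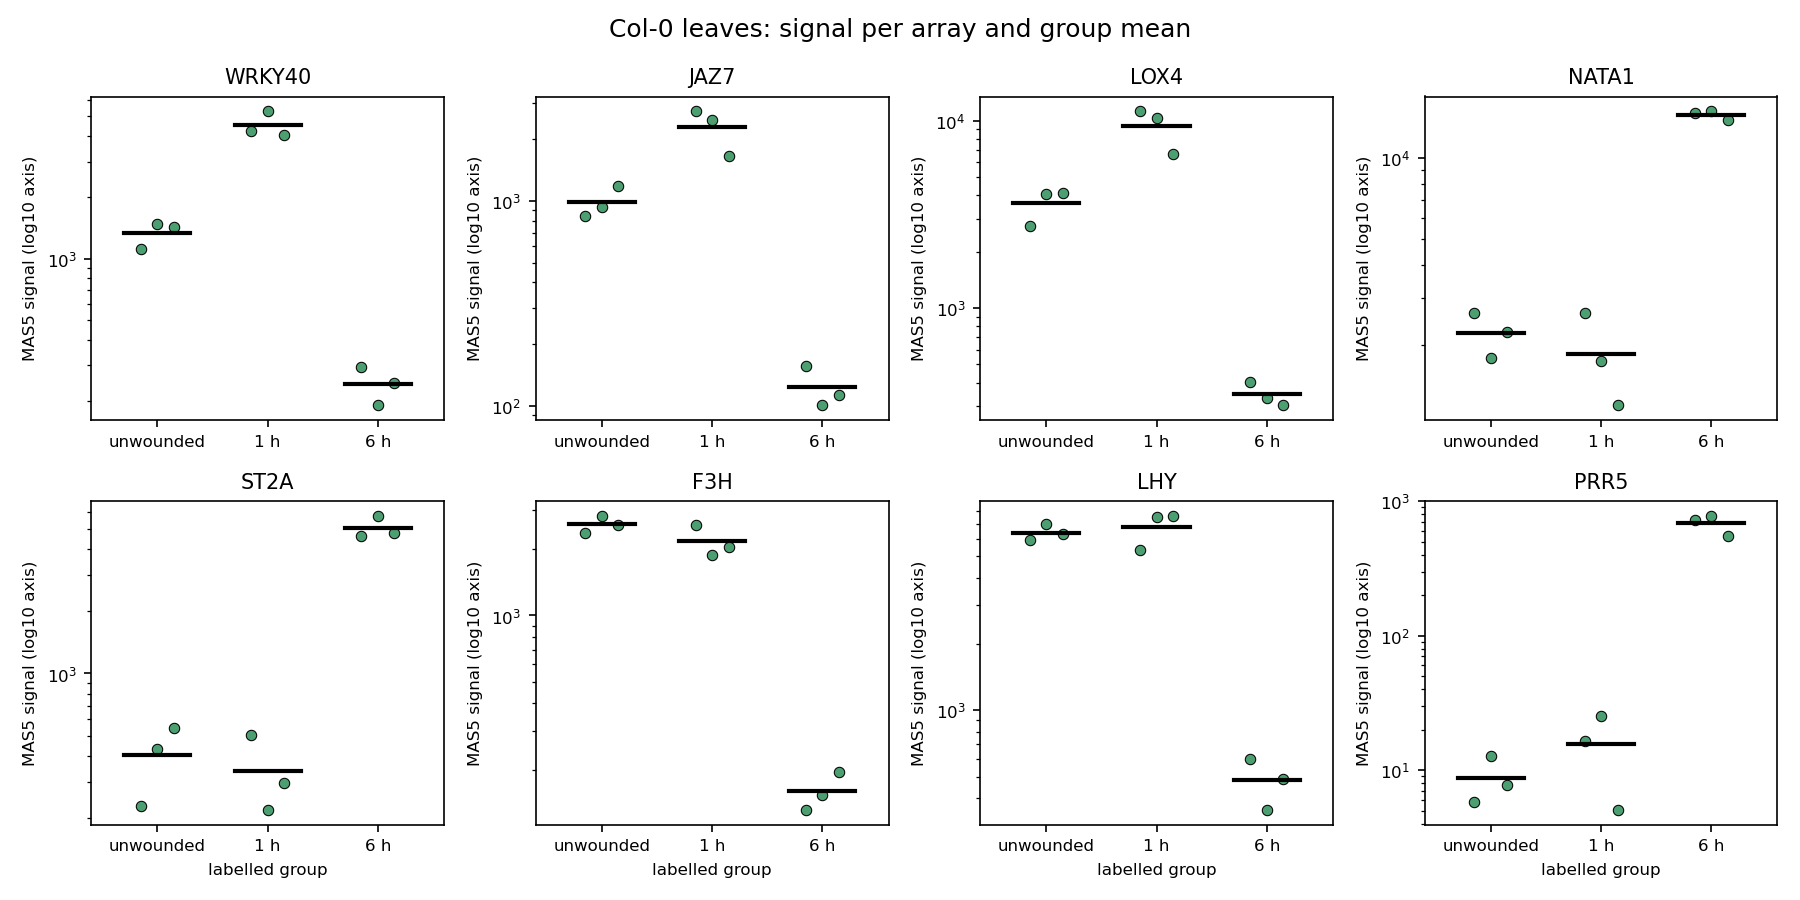
Signal of 8 genes on the 9 Col-0 arrays (log10 axis, MAS5 units), 1 point per array and a bar at the group mean, in unwounded leaves and at 1 h and 6 h after wounding. JAZ7 and WRKY40 are highest at 1 h and lowest at 6 h, NATA1 and ST2A are highest at 6 h, and LHY and PRR5 separate the 6 h arrays from the other 6.

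The difference between the early and the late state was tested directly by Col-0 leaves 6 h against 1 h after wounding. This was the largest contrast within Col-0, with 5392 probe sets passing, 3351 higher and 2041 lower at 6 h, and 2611 changed at least 2-fold. The ratio of 3' to 5' signal of actin, a sign of RNA quality, was 7.28 to 10.7 on the 1 h arrays and 4.12 to 6.97 on the 6 h arrays, and that of GAPDH 1.61 to 1.84 and 1.34 to 1.61. The median of all probe sets lay 0.13 above 0 on the log2 scale, and the share of passing probe sets that were higher went from 62.1% to 54.3% after quantile normalization and to 41.9% after subtraction of array medians. All 10 JAZ repressors were lower at 6 h than at 1 h, from JAZ7 (−4.22 ± 0.73, limma adjusted p = 0.00138) to JAZ12 (−0.91 ± 0.24). So were 12 of 16 touch and calcium genes, 11 of 16 WRKY factors and 8 of 10 C1-2i zinc finger genes. In the 18-array model the camera adjusted p was 3.78e-07, 5.68e-08, 3.5e-06 and 0.000262 for these 4 lists, adjusted p = 0.304, 0.291, 0.291 and 0.291 with an estimated correlation, and fry adjusted p = 0.00345, 0.00225, 0.00102 and 0.00102. The counts adjusted over the list alone were 10, 13, 11 and 8. Among the genes lower at 6 h were WRKY30, at least 8.03-fold, MYB47, at least 17.9-fold, and the calcium-binding protein gene AT3G01830 (−5.04 ± 0.80). The salicylic acid regulators WRKY54 (3.47 ± 0.81) and WRKY70 (1.81 ± 0.50) were higher at 6 h than at 1 h, as was ICS1 (1.11 ± 0.20). Of 15 jasmonate synthesis genes 7 were lower, LOX4 (−4.74 ± 0.80) and AOC3 (−4.04 ± 0.84) most, and 5 higher, while NATA1 (3.04 ± 0.45) and RNS1 (2.48 ± 0.59) were higher. Of 24 photosynthesis genes 13 were higher by 0.26 to 0.99, a count that was 10 after quantile normalization and 4 after subtraction of array medians. Of 13 aliphatic glucosinolate genes 7 were higher (4 after subtraction of array medians).

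Over-expression of StZFP2 was compared with the wild type over all conditions, as the mean of the 9 arrays labelled OE against the mean of the 9 Col-0 arrays. By construction this mean difference is the same whichever treatment an OE array received, but its standard error, adjusted p and count rest on the scatter within the labelled groups. With no term for treatment, an alternative chosen after seeing the data, 169 probe sets passed. In the model of 18 arrays, of 717 probe sets that passed, 446 were higher and 271 lower in OE, and 129 differed at least 2-fold. The mean 3' to 5' ratio of actin was 7.53 ± 2.17 in Col-0 and 5.42 ± 0.75 in OE, and that of GAPDH 1.56 ± 0.21 and 1.34 ± 0.12 (SD, n = 9 each). The share that was higher was 62.2%, 50.2% after quantile normalization and 35% after subtraction of array medians. The flowering repressor MAF5 (AT5G65080) was higher (limma adjusted p = 0.00399), but its Col-0 signals all lay below the 40th percentile of their arrays, so the size of its fold is not resolved. MEE3 (AT2G21650) was higher by 1.58 ± 0.17 (limma adjusted p = 0.000198) and the berberine bridge enzyme-like gene AT5G44400 by 1.46 ± 0.13 (limma adjusted p = 2.88e-05). In the unwounded groups AT5G44400 signal was 422 ± 103 in Col-0 and 1000 ± 191 in arrays labelled OE control (SD, n = 3 each). Among the lowest were the glutaredoxin genes AT4G15680 (−2.82 ± 0.37, limma adjusted p = 0.000979) and AT4G15690 (−1.95 ± 0.21, limma adjusted p = 0.000212). GRP5 (−2.15 ± 0.25, limma adjusted p = 0.000362), the iron-responsive gene AT1G47400 (−2.02 ± 0.24, limma adjusted p = 0.000415) and the chitinase-like gene AT2G43620 (−1.62 ± 0.14, limma adjusted p = 2.88e-05) were also lower. Each of these genes had 0 overlap between the 3 Col-0 and 3 OE arrays within every treatment label. The naming rule required this, so it is no separate support, and 28 genes met the whole rule. Within 1 label chance gives such separation to 10% of genes. This separation depends on the treatment labels as well.

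Camera called 4 of the 23 lists between the genotypes over all conditions, and 0 with an estimated correlation. Aliphatic glucosinolate genes, which make the methionine-derived defence compounds, were higher in OE for 3 of 13, GSTF11 (0.69 ± 0.15), the regulator MYB76 (0.60 ± 0.15) and BAT5 (0.55 ± 0.14), and for 10 adjusted over the list alone. Camera gave an adjusted p = 9.33e-05, adjusted p = 0.736 with an estimated correlation, and fry 0.0446. Of 16 WRKY factors WRKY53 (−0.72 ± 0.20), WRKY6 (−0.67 ± 0.18) and WRKY60 (−0.55 ± 0.14) were lower (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.00653, and adjusted p = 0.736 with an estimated correlation). Camera also called jasmonate breakdown and conjugation (0 of 9 passed) and photosynthesis (0 of 24 passed) as lower, with adjusted p = 0.0258 and 0.0133, and adjusted p = 0.736 for each with an estimated correlation. For jasmonate breakdown it gave adjusted p = 0.0907 after quantile normalization and 0.0944 after subtraction of array medians. For photosynthesis it gave 0.241 with the direction turned to higher, and 0.000433, in the same order. Of 17 ERF and CBF factors CBF2 (1.45 ± 0.34) and ERF105 were higher. Of 16 touch and calcium genes CML23, CAF1A and MPK3 were higher and CML42 lower, of which 1 and 0 of the 3 higher ones passed after quantile normalization and after subtraction of array medians. In the guard cell and phloem list KAT1 (0.63 ± 0.17) and MYB60 (0.45 ± 0.09), both guard cell genes, were higher, 2 of 4 (3 adjusted over the list alone; fry adjusted p = 0.00245, camera 0.0775). Of 10 C1-2i zinc finger genes and of 10 JAZ repressors 0 passed. With 1 array left out, the count was 415, 405 and 392 without Col-0 control B, Col-0 1h wound B and Col-0 1h wound C, and 428, 415 and 435 without Col-0 6h wound A, B and C. It was 387, 400 and 1087 without OE control A, B and C, and 464, 336 and 1440 without OE 1h wound A, B and C.

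**Figure D3:**
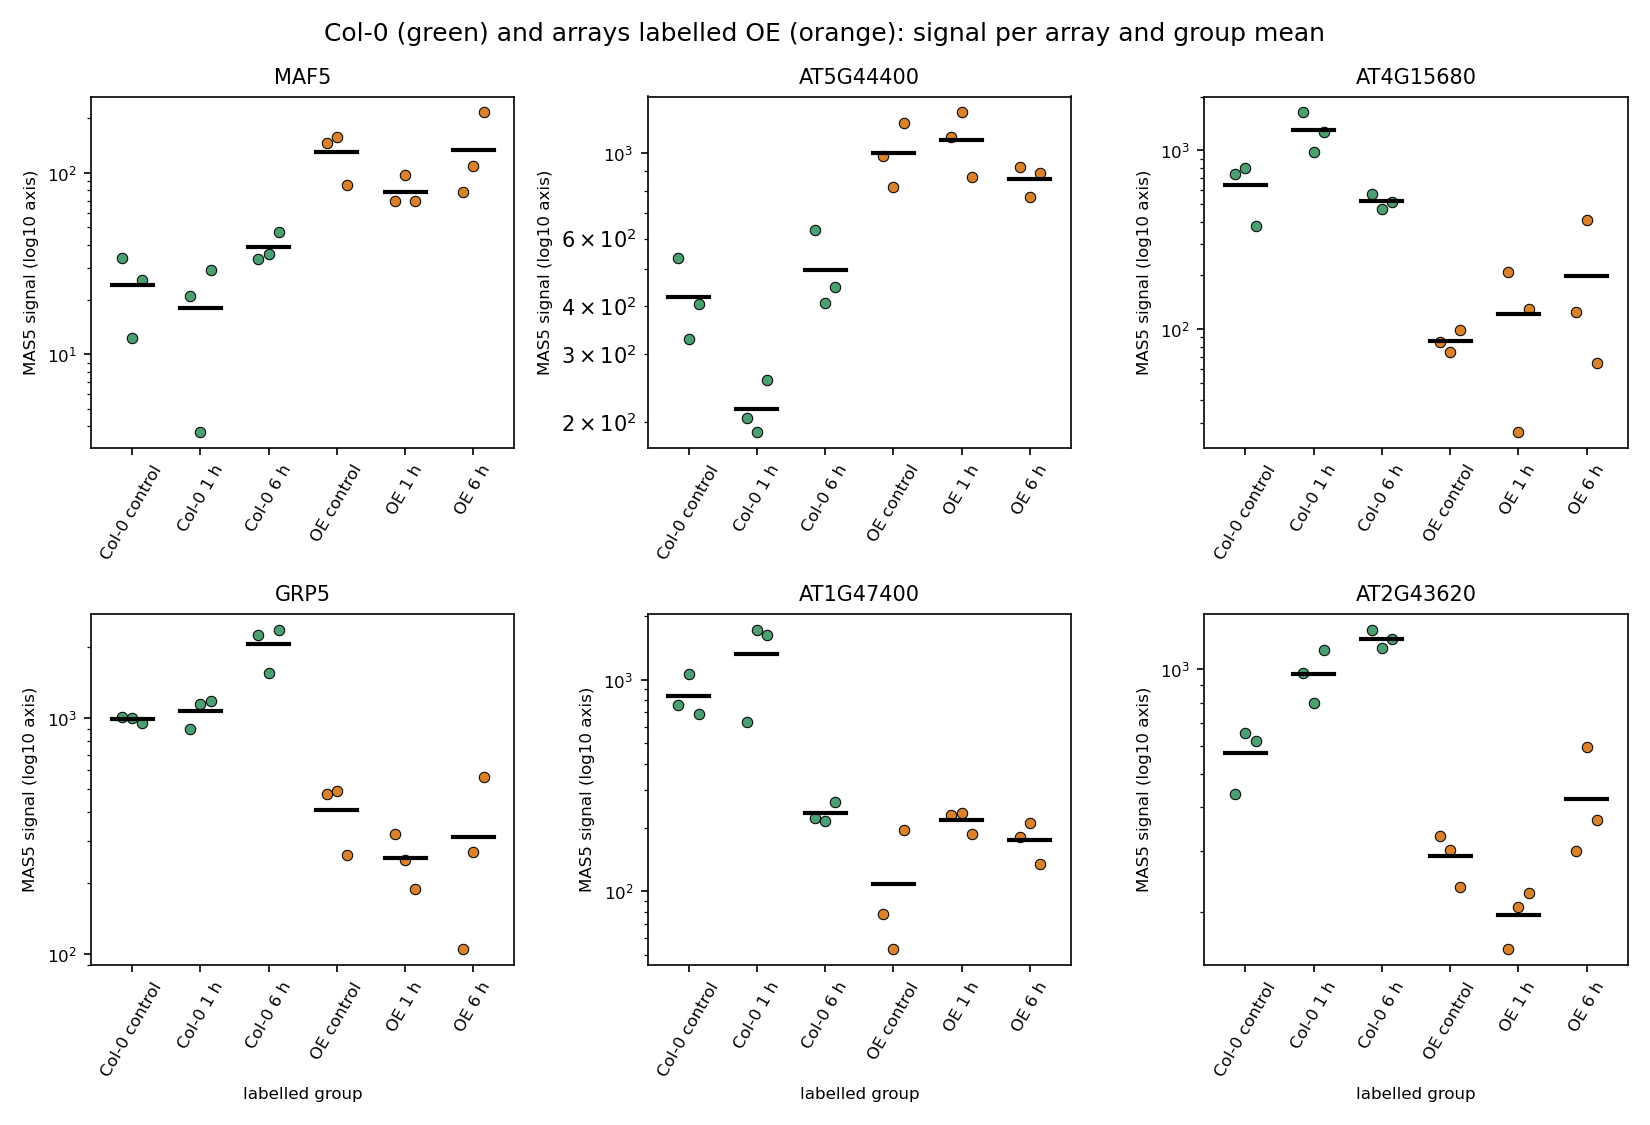
Signal of 6 genes on all 18 arrays (log10 axis, MAS5 units), 1 point per array and a bar at the mean of the 3 arrays of a labelled group, Col-0 at the left and OE at the right of each panel. MAF5 and AT5G44400 are higher and AT4G15680, GRP5, AT1G47400 and AT2G43620 lower in OE, with 0 overlap between genotypes within a treatment label.

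In the 3 comparisons of the genotypes within a treatment label, the mean differences themselves also rest on the treatment labels of the OE arrays. In unwounded leaves 1546 probe sets passed (926 higher and 620 lower in arrays labelled OE), at 1 h 1645 (983 and 662, with a median of all probe sets at 0.12), and at 6 h 157 (90 and 67). The 3' to 5' ratio of actin was 5.54 to 10.4 in Col-0 and 4.6 to 5.28 in OE in the unwounded groups, 7.28 to 10.7 and 4.97 to 6.13 at 1 h, and 4.12 to 6.97 and 4.45 to 6.74 at 6 h. That of GAPDH was 1.21 to 1.73 and 1.27 to 1.5, 1.61 to 1.84 and 1.31 to 1.47, and 1.34 to 1.61 and 1.18 to 1.28, in the same order. The share higher was 59.9%, 59.8% and 57.3%, and 45.4%, 36.1% and 44.9% after subtraction of array medians. In the unwounded comparison PRR5, at least 5.11-fold, PORB (3.98 ± 1.00) and AT2G39920, at least 13.5-fold, were higher in arrays labelled OE, and LHY (−3.15 ± 0.78), MYB47 (−3.49 ± 0.97) and FT (at least 1.52-fold) lower. PRR5, PORB, AT2G39920, LHY and MYB47 also separated the Col-0 6 h arrays from unwounded leaves, and the arrays labelled OE control A and B are those that matched the Col-0 6 h arrays. The unwounded count was 23 without OE control A, 22 without B and 3570 without C. At 1 h 10 of 16 WRKY factors were lower in arrays labelled OE, WRKY30 by at least 8.74-fold and WRKY18 by −2.93 ± 0.56 (camera adjusted p = 9.02e-10, adjusted p = 0.197 with an estimated correlation). At 1 h 10 of 13 aliphatic glucosinolate genes were higher (2 after subtraction of array medians; camera adjusted p = 5.17e-05, adjusted p = 0.382 with an estimated correlation). At 6 h 5 of 16 touch and calcium genes were higher (2 after subtraction of array medians), with CML12 at 1.98 ± 0.45 (camera adjusted p = 2.16e-12, adjusted p = 0.187 with an estimated correlation). At 6 h NATA1 (−1.96 ± 0.45) and GRP5 (−3.01 ± 0.43) were lower. For the unwounded comparison the count was 472, 145 and 319 without Col-0 control A, B and C. The count at 1 h was 945, 206 and 450 without Col-0 1h wound A, B and C and 146, 136 and 2919 without OE 1h wound A, B and C. The count at 6 h was 0, 4 and 0 without Col-0 6h wound A, B and C and 1, 5 and 3761 without OE 6h wound A, B and C.

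Wounding in the over-expressing lines was compared with their own control within the labels. At 1 h 0 probe sets passed in limma, with 2331 at an unadjusted p below 0.05, 1 without a variance trend, 4330 with array weights and 1590 without OE control C. Camera called 6 lists at 1 h, and 0 with an estimated correlation. Among them were JAZ repressors, higher, and sugar starvation genes, lower (adjusted p = 0.000967 for each, and adjusted p = 0.741 with an estimated correlation). The JAZ call was lost with array weights, with 15 arrays (the OE arrays lettered C left out) and without OE 1h wound C. At 6 h MYB108 (AT3G06490), at least 1.11-fold, and the ethylene synthesis gene ACS8, at least 2.41-fold, rose, 2 probe sets in all, with 2081 at an unadjusted p below 0.05. That count was 0 without OE control A or B or OE 6h wound A or B, and 2524 without OE 6h wound C. Of the fixed lists, camera called 11 at 6 h, against 0 with an estimated correlation and 0 with fry. The JAZ repressors came first (0 of 10 rose, 8 adjusted over the list alone; adjusted p = 1.67e-07, and adjusted p = 0.317 with an estimated correlation). The WRKY factors followed (0 of 16, 9 adjusted over the list alone; adjusted p = 1.44e-06, and adjusted p = 0.316 with an estimated correlation).

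Whether over-expression changed the wound response was tested by the interaction of genotype and wounding. At 1 h 0 probe sets passed in limma (1497 at an unadjusted p below 0.05; 416 without OE control C, 6 without OE 1h wound C, 2650 with array weights). Camera called 5 lists at 1 h, and 0 with an estimated correlation. The change was lower in arrays labelled OE for WRKY factors (adjusted p = 0.000103), sugar starvation (adjusted p = 0.00212) and heat shock (adjusted p = 0.00963), and higher for phenylpropanoids (adjusted p = 0.00212) and photosynthesis (adjusted p = 0.0434). With an estimated correlation these were 0.576, 0.702, 0.652, 0.576 and 0.751. The heat shock call was lost with the filter at the 60th percentile and without Col-0 control A or OE control C, and the photosynthesis call held in 11 of 27 settings. At 6 h 3460 passed, 1509 with a higher and 1951 with a lower change in arrays labelled OE than in Col-0. The change was higher for MYB47, WRKY30 and MAPKKK19 and lower for AT2G39920, PRR5 and PORB (limma adjusted p of the 6 genes between 0.00924 and 0.0111). The difference was −7.15 ± 1.42 for PORB. Each of the other 5 had a labelled group below the 40th percentile, so the size of its difference is not resolved. Of 10 JAZ repressors 9 passed, all higher (10 adjusted over the list alone; camera adjusted p = 1.28e-06, and adjusted p = 0.387 with an estimated correlation). Of 18 phenylpropanoid genes 9 passed, all higher (9 adjusted over the list alone; camera adjusted p = 3.13e-05, and adjusted p = 0.273 with an estimated correlation). Across the 2353 probe sets called at 6 h in either genotype, the log2 changes in arrays labelled OE and in Col-0 had a correlation of −0.853 and a slope of −0.421. Of these, 2351 were called in Col-0 and 2 in arrays labelled OE, so the set was chosen almost wholly by the change in Col-0. Other settings call other sets (7387 probe sets with array weights), so their slopes are not over the same genes. The slope was −0.647 without OE control C, −0.277 without OE 6h wound B and −0.821 without OE 6h wound C, and −0.921 with array weights, so the size of the slope is not settled. The changes thus ran in opposite directions under the labels as given, across genes, which are not independent replicates. At 1 h the correlation was 0.232 over 4 probe sets, too few to describe a relation. With array weights it was 0.0391 over 4900 probe sets, and without OE control C 0.0261 over 1611. With 15 arrays (the OE arrays lettered C left out) it was −0.0214 over 3598. The interaction count at 6 h was 2272 without Col-0 6h wound B, 1710 and 1691 without OE control A and B, and 1438, 1329 and 5676 without OE 6h wound A, B and C.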

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

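Chosen only after the results were seen were the tests of displaced treatment labels, of array quality and of a change shared by the arrays lettered C, the tests of the transgene and the tests of the clock genes; the regroupings of arrays were planned. The difference between the genotypes in the response to wounding at 6 h was marked by its own test, the interaction term, with 3460 probe sets. The log2 difference was 7.57 for MYB47, 7.05 for WRKY30, 6.93 for MAPKKK19, −9.84 for AT2G39920, −8.17 for PRR5 and −7.15 for PORB. Of these 6 all but PORB had a labelled group with each array below the 40th percentile, so the sizes of the other 5 are not resolved. No group held enough arrays for a test of single outlying samples.

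The pattern with the widest reach is that arrays labelled OE resemble arrays of other treatment labels. Among the 280 ways to part the 9 OE arrays into 3 sets of 3, the labelled one ranked 20 by variance within sets (0.229, against 0.117 in Col-0), and the one made by moving the labels 2 places along the list of arrays ranked 1 (0.0903). A candidate explanation is therefore that the treatment labels of the OE arrays are displaced, in which case the OE contrasts by treatment do not compare the treatments they name. Poor quality of the arrays lettered C is argued against by their closest matches, none below 0.974. The closest matches of the Col-0 arrays were 0.963 to 0.977, and the lowest correlation within a Col-0 group was 0.946. The matches had been seen before this test was chosen. The hybridisation controls of the array labelled OE control C had a mean of 1540, against 2252 to 2943 on the other arrays. A fault of that array thus stays open. A close match cannot show why it arose, so whether a fault bears on the match with other labels is not decided. The mean correlation among the arrays lettered C was 0.918, below that of each with its match under another letter. This argues against a shared change that outweighs the differences between treatments. A smaller shared change is not decided, because the 3 arrays carry different treatment labels. The arrays labelled OE 1h wound C and OE 6h wound A and B correlated at 0.953 to 0.971 with Col-0 1 h arrays. With unwounded and 6 h Col-0 arrays they reached 0.939 to 0.966 and 0.887 to 0.898. For OE control C and OE 1h wound A and B the values were 0.888 to 0.91, 0.93 to 0.948 and 0.92 to 0.94. In each set the highest value was with the Col-0 group that the moved labels name, though ranges of the nearest groups overlap. A displacement was found from these same data and stays a hypothesis. Neither the sample records nor the other columns were used to settle it.

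The opposite fold changes at 6 h are the second pattern. All 11 clock genes measured had fold changes of opposite sign at 6 h in the arrays labelled OE and in Col-0. Displaced labels would give such signs, since the arrays labelled OE control A and B were close to the Col-0 6 h arrays. The count restates the pattern for part of its genes, so it does not tell its causes apart. A biological explanation is that the transgene turns the response to wounding alone, in which case the OE controls would match the Col-0 controls. This is argued against by 2 of the 3 arrays labelled OE control. Arrays A and B correlated at 0.876 to 0.888 with the Col-0 controls and at 0.964 to 0.971 with the Col-0 6 h arrays. The same 2 of 3 arrays do not decide whether the transgene alters unwounded leaves as well as the response to wounding. An effect alike in all arrays of a label is argued against, for this pattern, by splits within labels. The array labelled OE control C correlated at 0.925 and 0.922 with OE control A and B. With OE 1h wound A and B it reached 0.974 and 0.973. The array labelled OE 6h wound C correlated at 0.89 with OE 6h wound A and B. With OE control A and B it reached 0.975 and 0.980. An effect that differs between arrays of a label stays open. OE control C correlated at 0.935 to 0.948 with the Col-0 controls and at 0.928 to 0.939 with the Col-0 6 h arrays. The treatment of an OE array is known from its label alone.

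Clock genes at 6 h in Col-0 are the third pattern. All 11 moved as they would between morning and evening, and 0 of the 11 were called at 1 h in the limma model of the 9 Col-0 arrays, where the largest change was 1.22 in size on the log2 scale. Harvest at another time of day than the unwounded leaves may account for the clock genes and for an unknown part of the other changes at 6 h. Wounding itself stays open for them, because the labels name no unwounded group at 6 h and give no hour of harvest.

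Other divisions of the same arrays were fitted for each count. With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. At 1 h in Col-0 the real count was 4 and the highest other 0, at 6 h in Col-0 2351 and 0, between 6 h and 1 h 5392 and 0, in unwounded leaves of the genotypes 1546 and 4, at 1 h 1645 and 0, and at 6 h 157 and 0, each with 1 split as large, the real one. In OE at 1 h the real count was 0 and the highest other 242, with 10 splits as large, and in OE at 6 h the real count was 2 and the highest other 4161, with 2 as large. Splits of the OE arrays that call many times the real count point to a structure of the samples that the labels do not follow.

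With 100 regroupings within treatment labels, including the real grouping, 1 was as large for the interaction at 6 h (3460, highest other 2671). For the genotypes over all conditions 2 were as large (717, highest other 2303). Counts of this size were thus rare among the regroupings, but chance is not excluded. The regroupings keep the treatment labels of the OE arrays, which may be displaced, and for the genotypes another regrouping exceeded the real count. For the interaction at 1 h the real count was 0, so all 100 are as large whatever the arrays show, and the comparison decides nothing (highest other 1006). The regrouping with 2303 points to a structure of the samples, and the arrays that carry it were not traced.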

How the results depend on the processing

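Of the alternatives, the models of the 9 Col-0 arrays, of 15 arrays without the OE arrays lettered C and of 9 against 9 arrays with no term for treatment were chosen after seeing the data. Of 142 values under alternatives, 94 stayed within 1.5 times the reported count or within 1 SD and 48 did not; of 126 values with 1 array left out, 66 did and 60 did not. The count at 6 h against 1 h in Col-0 held under each alternative run (4631 to 7479), and the correlation of the responses at 6 h was negative under each (−0.886 to −0.803), while its slope, reported as −0.421, was −0.921 with array weights and −1.04 with the 15 arrays. Array weights gave 760 probe sets at 1 h and 5044 at 6 h in Col-0, and 4330 and 6076 in OE. They gave 6691, 5099 and 5358 for the genotypes unwounded, at 1 h and at 6 h, 3112 over all conditions, and 2650 and 7755 for the interactions at 1 h and 6 h. The 15 arrays gave 1201 and 4816, 2720 and 4777, 5236, 4769 and 5048, 2323, and 2330 and 6910 in the same order. The 9 Col-0 arrays gave 866 at 1 h and 4294 at 6 h. These 3 settings down-weight or leave out OE arrays that scatter, but the cause of their counts was not tested. With the 15 arrays the OE controls were A and B, which matched the Col-0 6 h arrays. The larger OE counts and the steeper slope thus still rest on the treatment labels. They cannot be read as a wound response cleared of noise. Array weights also gave low weight to Col-0 control A and C (0.598 and 0.625). With no term for treatment 169 passed over all conditions, because treatment then adds to the spread. A model of only the arrays compared gave 582 at 1 h and 3839 at 6 h in Col-0, 0 at 6 h in OE, and 1012, 924 and 29 for the genotypes unwounded, at 1 h and at 6 h. The replicate block gave 0 at 1 h in Col-0, 1 at 6 h in OE, 643 for the genotypes unwounded and 7 at 6 h. Quantile normalization gave 2 at 1 h in Col-0 and 1 at 6 h in OE; subtraction of array medians gave 10 and 1. No filter gave 5 at 6 h in OE, 933 unwounded and 73 at 6 h between genotypes, the filter at the 60th percentile 0 at 6 h in OE, and no variance trend 1 at 1 h in OE and 69 at 6 h between genotypes. For these the cause was not tested. The correlation of the responses at 1 h was 0.737 over 4 probe sets after addition of 16 and turned to −0.0271 over 3 without a filter. It was −0.0214 over 3598 probe sets with 15 arrays and 0.0391 over 4900 with array weights. It had no value under the replicate block, quantile normalization and the arrays compared, where fewer than 3 probe sets were called. List calls went from 91 to 0 with an estimated correlation and to 31 with fry. With 1 array left out the ranges were 0 to 5 and 439 to 1579 at 1 h and 6 h in Col-0, 3774 to 4278 at 6 h against 1 h, and 0 to 1590 and 0 to 2524 in OE. For the genotypes they were 22 to 3570 unwounded, 136 to 2919 at 1 h, 0 to 3761 at 6 h and 336 to 1440 over all conditions, and 0 to 416 and 1329 to 5676 for the interactions. They were −0.266 (without OE 1h wound C, reversed) to 0.827 and −0.917 to −0.746 for the correlations at 1 h and 6 h, and 79 to 106 list calls. No named gene changed sign under an alternative or with 1 array left out, but calls were lost. They were lost in 315 of 1374 checks of called genes at 6 h in Col-0, 30 of 67 at 1 h in Col-0, 14 of 30 at 6 h in OE and 0 of 203 at 6 h against 1 h. For the genotypes they were lost in 31 of 95 unwounded, 6 of 32 at 1 h, 24 of 48 at 6 h and 208 of 1181 over all conditions, and in 0 of 132 for the interaction at 6 h. At 1 h in Col-0 the 67 checks cover only the 4 genes called in the reported model, of 33 named. The rest were named from the model of the 9 Col-0 arrays. Over all 33 genes a call was gained in 86 of 556 checks. The model of the 9 Col-0 arrays was not itself run with another scaling or with 1 array left out. Dim signals limit the folds given as lower bounds. The series matrix in place of the MAS5 table was not run, because it is the source already used.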

Other observations

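The tests of gene ontology terms, the genes named here outside the fixed rule and the test of neighbouring genes were all chosen after the results were seen. Terms were tested over 9028 genes with Benjamini-Hochberg adjustment over 712 terms. Fisher's exact test counts genes as independent draws, so its p-values take no account of the arrays or of genes that move together. They describe the sets of called genes and are no measure of replication. No test of the terms with an estimated correlation between genes was run. At 1 h in the model of the 9 Col-0 arrays, genes that rose held 39 of the 95 genes of response to chitin, where chance gives 3.91 (Fisher's exact test, one-sided, adjusted p = 8.52e-27), and 25 of 117 of response to wounding (adjusted p = 2.41e-09).

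At 6 h in Col-0 the genes that rose in the 18-array model held 7 of the 14 genes of starch breakdown, where chance gives 1.28 (Fisher's exact test, one-sided, adjusted p = 0.0365). They were DPE1 (3.65), AMY3 (3.14), SEX1 (2.81), DPE2 (2.62), SEX4 (2.25), BAM5 (1.59) and LSF1 (0.70 on the log2 scale). The model of the 9 Col-0 arrays gave 12 of 14 (adjusted p = 5.87e-06). It also gave 10 of 18 autophagy genes, where chance gives 2.86 (adjusted p = 0.0151), a term that did not pass at 6 h against unwounded leaves in the 18-array model. These genes included ATG8E (1.43), ATG8F (1.17) and ATG3 (0.82). Genes that fell in the 18-array model held 28 of 114 of response to heat (chance 8.46, adjusted p = 7.36e-06), 26 of 117 of response to wounding (chance 8.68, adjusted p = 0.000107) and 11 of 35 of response to UV-B (chance 2.6, adjusted p = 0.00395). The labels name no unwounded group at 6 h, so these values do not separate wounding from time of day.

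Over all conditions, genes lower in OE held 7 of 49 genes of lipid transport (chance 1.08, Fisher's exact test, one-sided, adjusted p = 0.0337) and 9 of 88 of response to salicylic acid (adjusted p = 0.0337). They also held 9 of 89 of lipid synthesis (adjusted p = 0.0337) and 9 of 97 of fatty acid synthesis (adjusted p = 0.0489). The genes of the lipid terms included KCS3 (−0.98), KCS2 (−0.93), KCS1 (−0.90) and CER4 (−0.92), which make the long chains and alcohols of surface wax. The lipid transfer genes EARLI1 (−1.18) and LTPG1 (−0.79) were also lower. Among genes higher in OE 0 terms passed, the lowest adjusted p being 0.0684.

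Single genes of flowering and of iron were picked by hand after the results, and neither set was tested as a list. Beside MAF5, the flowering repressor MAF4 was higher in OE (limma adjusted p = 0.0243) and the flowering signal FT lower (limma adjusted p = 0.0194). The Col-0 signals of MAF4 and the OE signals of FT lay below the 40th percentile, so the sizes are not resolved. Of the others, MAF1 (0.08), SOC1 (0.20) and FUL (−0.79) did not pass. Of the genes tied to iron, those lower in OE were BHLH39, dim in 4 of the 6 groups, FRO3 (−1.04 ± 0.15), OPT3 (−0.95 ± 0.18), BTS (−0.93 ± 0.15) and PYE (−0.83 ± 0.20), with limma adjusted p between 0.00171 and 0.0287. The iron stores FER1 (0.44), FER3 (−0.22) and FER4 (0.42), and NAS4 (−0.22), did not pass.

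Called genes of the genotype contrast over all conditions may lie next to each other in the genome, a structure that an insertion, a deletion or a stretch from another accession could leave. Of 13987 genes ordered on the chromosomes 686 were called, and 33 pairs of neighbouring genes were called with the same sign, where permutations gave a mean of 17.7 and a highest of 36 (10000 permutations, permutation p = 6e-04). Among the pairs were MAF4 and MAF5, the run of glutaredoxin genes AT4G15660, AT4G15680, AT4G15690 and AT4G15700, and the receptor kinases AT1G51790 and IOS1 (−1.08 and −1.66). Such neighbours are often copies with shared regulation, so the excess is consistent with joint regulation of copies as well, which was not tested.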
